A study of Homo sapiens with 12 samples.

How the data were processed

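RNA from the human glioblastoma line LN229 was measured on 12 arrays, 3 in each of 4 groups. Per the labels' protocols, cells were transfected with siRNA 24 h after seeding, moved 48 h later to 1% or 20% oxygen, and harvested after 16 h. RNA was purified with a Qiagen kit and labelled by the Affymetrix whole transcript sense target assay. The groups were normoxia with control siRNA, hypoxia with control siRNA, hypoxia with siRNA against HIF1A, and hypoxia with siRNA against HIF2A (gene symbol EPAS1). Labels number the replicates in each group 1 to 3. Nothing in the labels says that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

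The deposited values were treated as log2 expression, with 1 value per probe set and array. The scale was read from the values, which ran from 1.14 to 14.3 with decimals; base 2 was inferred, because another common base would put the brightest values above a scanner's range. The submitters' processing notes name Partek and the genome build hg18. Background correction, summarization, normalization and filters are not given in the sources used here. Array medians lay between 6.49 and 6.82, and upper quartiles between 7.88 and 8.57, so the deposited values had no common distribution over these probe sets. No change of scale was made before the tests.

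The deposited values covered 22011 probe sets. The platform annotation pairs 14432 of them with 1 gene symbol, 2408 with several and 5171 with none here. Gene IDs of the single-symbol probe sets were looked up in a RefSeq gene table of GRCh38.p14, where 14404 were found, and 0 symbols needed an update. For the 197 genes with more than 1 single-symbol probe set, the probe set with the highest mean over all arrays was used, without regard to the others. This left 14232 genes. Each probe set has a single value per array, summarized by the submitters in a way not given here, so splice forms were not separated. No genome positions were used.

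Differences between groups were tested with limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table to read and join tables and matplotlib 3.10.9 for the plots. A mean was fitted for each group over all 12 arrays and 22011 probe sets, variances were moderated with eBayes, and p-values were adjusted by Benjamini and Hochberg over the 14232 genes within each comparison. A gene was called at an adjusted p under 0.05. Errors of log2 changes are limma's standard errors (SE), with n = 3 arrays per group. The number of arrays limits the precision. On simulated data with known changes (14232 genes, 200 of them changed), calls recovered 53.7% of 1.5-fold, 88.1% of 2-fold and 100% of 4-fold changes for hypoxia against normoxia. The same shares were 46.3%, 83.6% and 98.5% for HIF1A siRNA against control siRNA, and 43.3%, 88.1% and 98.5% for HIF2A siRNA against control siRNA. False calls were 9 of 170, 9 of 161 and 14 of 167. The simulated noise was independent between genes. Differences in range between whole arrays were not simulated, so these figures do not cover them.

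Hypoxia-induced genes were those called higher in hypoxia with at least a 1.5-fold rise, and each was sorted by whether it was also lower with either siRNA. The share of the rise left with an siRNA is the log2 change from normoxia with that siRNA divided by the log2 change with control siRNA, as a percent. It was taken over all induced genes except EPAS1, a target of the siRNAs. Comparisons that share the hypoxic control arrays were set against 100 simulated draws of an unchanged group.

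A set of 34 gene lists was tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists within a comparison, again with an estimated correlation, and with fry. Fry asks whether the genes of a list move one way on balance and compares them with no other genes. The lists cover glycolysis, glycogen metabolism, pH regulation, the HIF pathway, oxygen-dependent demethylases, angiogenic factors, collagen and matrix, mitophagy and the BNIP3 family, a tumour hypoxia classifier, genes known for a HIF-1A or for a HIF-2A preference, oxidative phosphorylation, the tricarboxylic acid cycle, G1/S, G2/M, DNA repair, ribosome biogenesis, the unfolded protein response, ATF4-linked genes, cholesterol and fatty acid synthesis, lipid storage, interferon response, small RNA machinery, p53 targets, NF-kB factors, mesenchymal genes, neural stem genes, markers of astrocytes, neurons, oligodendrocytes, microglia, endothelium and epithelium, and housekeeping genes. Lists overlap: the classifier, the HIF-1A preference list and the glycolysis list share members.

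The groups, the tests, the lists, most of the other settings and the rule for named genes were chosen before the data were examined. The rule names HIF1A and EPAS1. For hypoxia and for each siRNA against control siRNA it adds the 10 called genes with the largest rise and the 10 with the largest fall whose 3 values in one group all lie above those of the other; for the other comparisons it adds 5 of each. It also takes the 10 induced genes most lowered by each siRNA relative to the other, and from each list the 4 called members with the largest change, or those with the smallest adjusted p where fewer pass. Other settings were all probe sets, a filter that kept genes above the 25th percentile of an array on at least 3 arrays, quantile normalization, centring on array medians, an intensity trend, no variance moderation, a fit of the compared groups alone, the replicate number as a block, array weights, other thresholds, and leaving out each array in turn. Cyclic loess normalization, and quantile normalization without the third HIF1A siRNA array, were added after the data had been seen. All 12 arrays were used.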

Results

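LN229 is an established human glioblastoma cell line. Transcripts were measured on 12 arrays, 3 each from cells in 20% oxygen with control siRNA, and from cells in 1% oxygen with control siRNA, HIF1A siRNA or HIF2A siRNA. HIF1A and EPAS1 encode HIF-1A and HIF-2A, the oxygen-regulated subunits of the hypoxia-inducible transcription factors, and the study asked which hypoxic responses depend on which subunit. Arrays of the same group correlated across probe sets at r = 0.983 to 0.994. Between their quartiles the HIF1A siRNA arrays had a narrower range than the others, most clearly the third. Their upper quartiles were 8.22, 8.20 and 7.88 on the log2 scale, against 8.50, 8.27 and 8.34 for hypoxia with control siRNA and 8.44, 8.24 and 8.44 for HIF2A siRNA. The SD over all probe sets was 2.453 for HIF2A siRNA replicate 2, below 2.463 and 2.455 for HIF1A siRNA replicates 1 and 2.

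**Figure D1:**
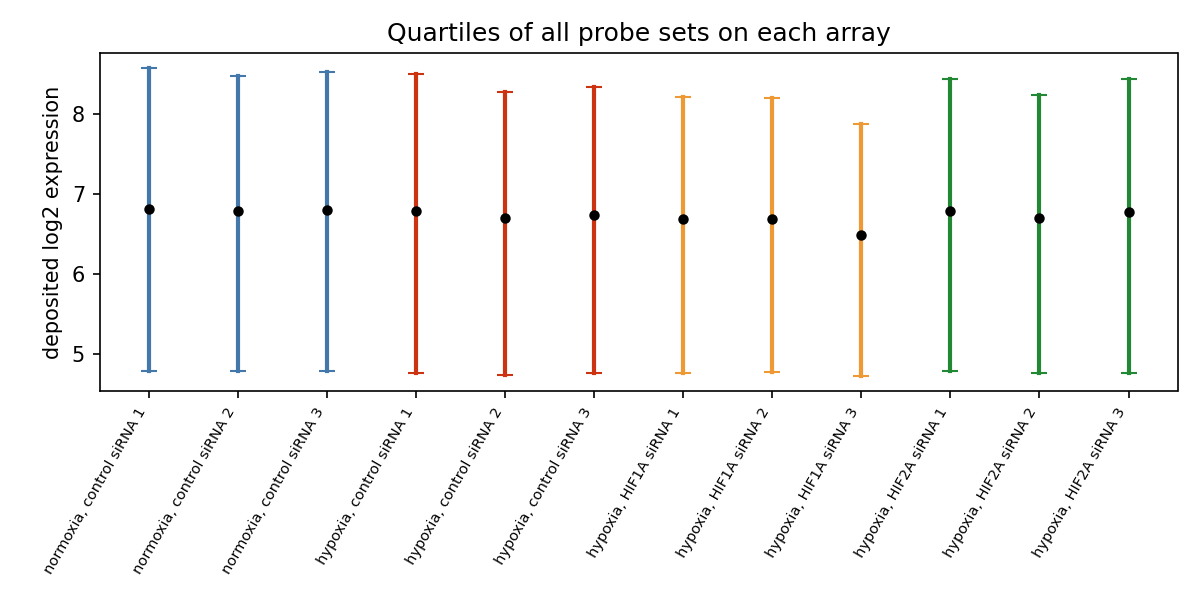
Deposited log2 expression of all probe sets on each of the 12 arrays, with lines from the lower to the upper quartile and a dot at the median, coloured by group. The third HIF1A siRNA array has the lowest upper quartile, 7.88, and the normoxic arrays reach 8.57, 8.47 and 8.52.

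The targeted transcripts were lower in the groups labelled with their siRNA. HIF1A measured 11.7, 11.4 and 11.3 in hypoxia with control siRNA and 8.20, 9.06 and 7.74 with HIF1A siRNA, a fall of 8.76-fold (log2 change -3.13, SE 0.27, n = 3 per group, adjusted p = 1.6e-04) that left 11.4% of the transcript. With HIF2A siRNA it measured 11.3, 11.0 and 11.4, which was not called different from control siRNA (log2 change -0.21, SE 0.27), and hypoxia itself gave -0.06 (SE 0.27, adjusted p = 0.931). EPAS1 rose 2.29-fold in hypoxia, from 8.52 ± 0.09 to 9.71 ± 0.13 (mean ± SD, n = 3; adjusted p = 7.1e-04). HIF2A siRNA lowered it 6.04-fold to 7.12 ± 0.11 (log2 change -2.59, SE 0.15, adjusted p = 3.1e-05), which left 16.6%. EPAS1 was also lower with HIF1A siRNA, at 8.23 ± 0.32 (log2 change -1.48, SE 0.15, adjusted p = 3.1e-04), on each of the 3 arrays below each control array, and it stayed 2.16-fold above its level with HIF2A siRNA (adjusted p = 0.0017).

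**Figure D2:**
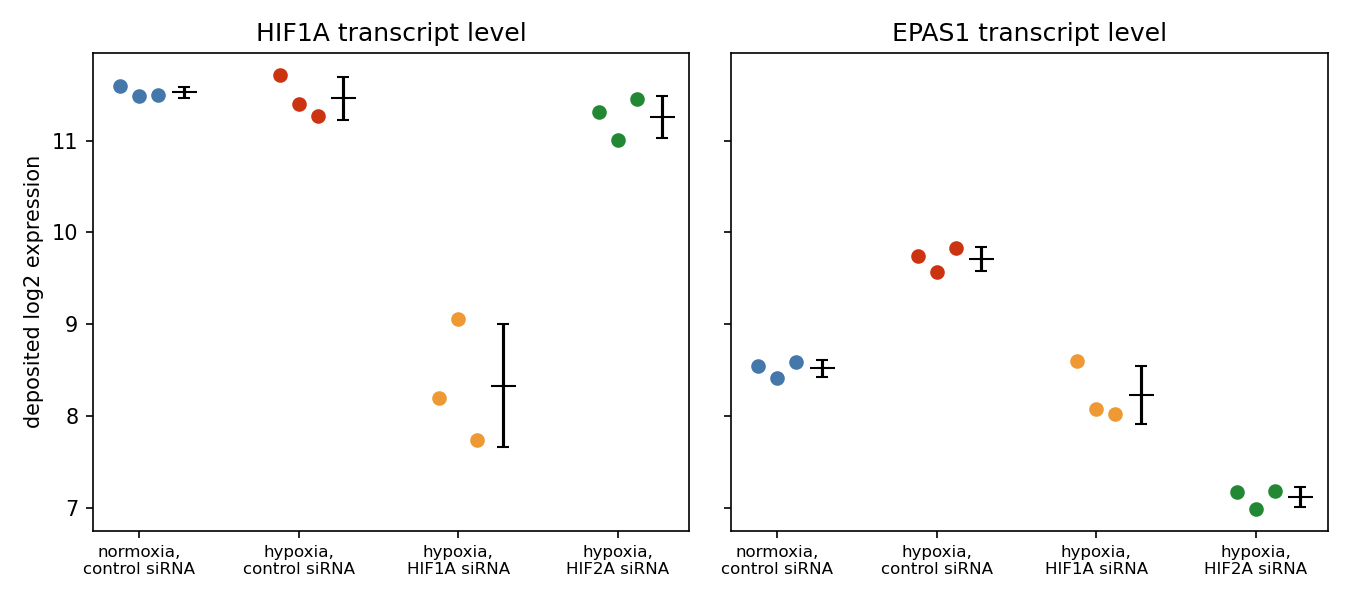
Deposited log2 expression of HIF1A and EPAS1 in the 4 groups, with a dot for each array and a black mark for the mean ± SD (n = 3). HIF1A averages 8.33 with HIF1A siRNA and 11.3 with HIF2A siRNA, the next lowest group, and EPAS1 is lowest with HIF2A siRNA, at 7.12.

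Among the largest rises in hypoxia were genes of glycolysis and of secreted factors. BEND5, a BEN domain gene, rose 15.2-fold (log2 change 3.93, SE 0.21, n = 3 per group, adjusted p = 2.1e-06). ALDOC, a glycolytic aldolase, rose 10.9-fold (3.45, SE 0.15, adjusted p = 5.5e-07). The secreted factors ANGPTL4, a regulator of lipoprotein lipase, and STC1, a stanniocalcin hormone, rose 10.0-fold and 9.73-fold, and NDRG1, a stress-response gene, rose 8.67-fold (3.12, SE 0.11, adjusted p = 1.2e-07). NRN1, TMEM45A, ENO2, DEPP1 and CP completed the 10 largest rises, with log2 changes of 3.16, 2.93, 2.77, 2.76 and 2.63. The largest fall was that of HMGCS1, which makes HMG-CoA for cholesterol synthesis, at 4.00-fold (SE 0.19 on the log2 scale, adjusted p = 1.1e-04). MRGPRX4 (-2.0), SPC25, a kinetochore gene (-1.87), TAF9B, a TFIID subunit (-1.85), CTPS1, which makes CTP (-1.74), TMEM100 (-1.72), THEM4 (-1.69), CDC25A, a cell-cycle phosphatase (-1.58), and the chemokine CCL2 (-1.56) also fell. The histone gene H2BC3 belonged to these 10 at -1.97, but lost its call without hypoxia control replicate 2 or any normoxia replicate, with a highest adjusted p of 0.083. The deposited values hold no measure of background, and MRGPRX4 and TMEM100 averaged 4.60 and 4.44 in hypoxia, below the lower quartile of every array (4.73 to 4.79), so the size of their falls is uncertain.

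Genes of glycolysis and glycogen metabolism were among the rises. Of 19 measured glycolytic genes, 13 rose and 0 fell (14 and 1 adjusted over the list alone; median 1.18, camera adjusted p = 8.1e-23, adjusted p = 0.0772 with an estimated correlation), led by ALDOC, ENO2 (2.77), PDK1, which restrains pyruvate oxidation (2.15), and PFKFB4 (2.02). Of 8 genes of glycogen metabolism, 5 rose and 1 fell, the same over the list alone (median 1.02, adjusted p = 6.1e-06, adjusted p = 0.217 with an estimated correlation). PPP1R3C, a glycogen-targeting phosphatase subunit, rose by 2.13 and glycogen synthase GYS1 by 1.96. Of 4 genes of pH regulation, the carbonic anhydrase CA12 rose (0.53) and none fell, with 1 rise and 1 fall over the list alone (median -0.06, adjusted p = 0.728).

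Other lists linked to HIF passed camera as rises. In the HIF pathway list, 5 of 12 members rose and 0 fell, the same over the list alone (median 0.19, adjusted p = 2.5e-04, adjusted p = 0.259 with an estimated correlation), among them the repressors MXI1 (1.5), BHLHE41 (1.22) and BHLHE40 (1.13). Of 13 oxygen-dependent demethylases, 7 rose and 0 fell by either adjustment (median 0.49, adjusted p = 1.5e-07, adjusted p = 0.223 with an estimated correlation), led by TET1 (1.85) and the histone demethylases KDM4C (1.24) and KDM3A (1.02). Of 25 angiogenic and secreted factors, 10 rose and 0 fell (13 and 0 over the list alone; median 0.35, adjusted p = 3.1e-13, adjusted p = 0.129 with an estimated correlation), including VEGFA, the main endothelial growth factor (2.37), and IGFBP3 (1.94). Of 22 collagen and matrix genes, 11 rose and 0 fell (14 and 0 over the list alone; median 0.38, adjusted p = 1.4e-12, adjusted p = 0.101 with an estimated correlation). The collagen-modifying enzymes P4HA1 (2.07), P4HA2 (1.46) and PLOD1 (1.14) led them. The mitophagy list had 4 rises and 0 falls among 11 members (5 and 1 over the list alone; median 0.31, adjusted p = 9.1e-05, adjusted p = 0.138 with an estimated correlation), in FAM162A (2.62), DDIT4, an inhibitor of mTORC1 (2.05), BNIP3L (1.88) and BNIP3 (1.84).

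The tumour hypoxia classifier had 11 rises among 13 members by either adjustment (median 1.76, adjusted p = 1.0e-20, adjusted p = 0.0516 with an estimated correlation). Genes known for a HIF-1A preference had 14 rises among 18 by either adjustment (median 1.48, adjusted p = 2.7e-27, adjusted p = 0.0516 with an estimated correlation). Neither list had a fall. Genes known for a HIF-2A preference had 2 rises and 0 falls among 17 by either adjustment (median 0.03, adjusted p = 0.228): LOXL2, a lysyl oxidase (0.98), and the VEGF receptor FLT1 (0.79), which lost its call without hypoxia control replicate 1 or 2 or any normoxia replicate (highest adjusted p 0.0925). ATF4-linked genes of the amino acid response had 12 rises and 0 falls among 25 (15 and 0 over the list alone; median 0.50, adjusted p = 2.4e-14, adjusted p = 0.157 with an estimated correlation), led by the lipoprotein receptor VLDLR (2.40), STC2 (1.40) and PSAT1, of serine synthesis (1.23). The mesenchymal list had 3 rises and 0 falls among 22 by either adjustment (median 0.11, adjusted p = 0.00977, adjusted p = 0.519 with an estimated correlation), among them the fibronectin receptor subunit ITGA5 (0.70) and fibronectin itself, FN1 (0.64), but did not pass fry (adjusted p = 0.157).

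DNA replication genes formed the largest group of falls. Of 30 genes of G1/S and replication, 26 fell and 0 rose (29 and 0 over the list alone; median -0.96, adjusted p = 1.5e-20, adjusted p = 0.168 with an estimated correlation), including the checkpoint adaptor CLSPN (-1.35), the clamp loader subunit RFC3 (-1.29) and the polymerase subunit POLE2 (-1.28). Of 28 G2/M genes 4 fell and 0 rose (13 and 0 over the list alone; median -0.46, adjusted p = 1.5e-04, adjusted p = 0.633 with an estimated correlation), and each of the 4, CCNA2, KIF2C, NEK2 and AURKB, lost its call without hypoxia control replicate 2 or normoxia replicate 1 (highest adjusted p 0.132). The list did not pass fry (adjusted p = 0.0956). Of 11 DNA repair genes, 6 fell and 0 rose (8 and 0 over the list alone; median -0.67, adjusted p = 6.1e-06, adjusted p = 0.259 with an estimated correlation), among them RAD54L (-1.01), XRCC2 (-0.91) and BARD1 (-0.76). The ribosome biogenesis list had 6 falls and 0 rises among 14 (9 and 1 over the list alone; median -0.51, adjusted p = 3.1e-04, adjusted p = 0.310 with an estimated correlation), led by RRS1 (-1.18) and WDR12 (-1.07). Of 19 genes of cholesterol and fatty acid synthesis, 13 fell and 0 rose by either adjustment (median -0.64, adjusted p = 1.2e-08, adjusted p = 0.217 with an estimated correlation). After HMGCS1 came the fatty acid elongase ELOVL6 (-1.36) and squalene epoxidase SQLE (-1.33).

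Mitochondrial genes shifted less. Of 27 nuclear genes of oxidative phosphorylation, 4 fell and 0 rose (5 and 0 over the list alone; median -0.27, adjusted p = 0.0285, adjusted p = 0.665 with an estimated correlation), including COX7B (-0.87) and CYC1 (-0.69). Of 12 genes of the tricarboxylic acid cycle, 4 fell and 0 rose (5 and 0 over the list alone; median -0.33, adjusted p = 0.0171, adjusted p = 0.633 with an estimated correlation). SUCLG1, PDHB, OGDH and IDH3B each lost the call without hypoxia control replicate 2 or normoxia replicate 1 or 3 (highest adjusted p 0.116). These list calls were lost with fry (adjusted p = 0.0956 and 0.0618), with quantile normalization (medians -0.14 and -0.23, adjusted p = 0.118 and 0.0745) and with cyclic loess (-0.12 and -0.18, adjusted p = 0.219 and 0.138). The first was also lost without normoxia replicate 1 (adjusted p = 0.0571), and the second without hypoxia control replicate 3 (adjusted p = 0.0506).

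Several lists did not pass camera in hypoxia. Lipid storage had 2 rises and 4 falls among 12 members (2 and 5 over the list alone; median -0.01, adjusted p = 0.707), with the lipid droplet gene HILPDA up by 2.53 and the phosphatidate phosphatase LPIN1 down (-0.81). The interferon list had 7 falls and 0 rises among 24 (8 and 2 over the list alone; median -0.15, adjusted p = 0.130), among them the RNA sensor TLR3 (-1.07) and IFIT3 (-0.78), and passed fry as a fall (adjusted p = 0.0194). NF-kB factors had 3 rises and 2 falls among 19 by either adjustment (median -0.04, adjusted p = 0.391), the cyclooxygenase PTGS2 (2.17) and IL1A (1.38) against CCL2. The unfolded protein response had 1 rise and 1 fall among 19 by either adjustment (median 0.05, adjusted p = 0.237), and passed as a rise with quantile normalization (median 0.20, adjusted p = 0.0210) and cyclic loess (median 0.21, adjusted p = 0.00966). Of 17 p53 targets 2 fell and 0 rose (5 and 0 over the list alone; median -0.19, adjusted p = 0.166). Neural stem genes had 1 rise, the adhesion molecule L1CAM (0.68), and 3 falls among 16 (2 and 4 over the list alone; median -0.14, adjusted p = 0.673).

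The small RNA machinery had 0 calls among 11 with limma by either adjustment (median -0.17, adjusted p = 0.566), and its members with the lowest values, DROSHA and XPO5, stood at -0.59 and -0.37. Astrocyte markers had 1 fall among 8, S100B (-0.63), by either adjustment (median 0.04, adjusted p = 0.673). Markers of neurons (8 measured, median -0.06, adjusted p = 0.994), oligodendrocytes (8, median -0.17, adjusted p = 0.563), microglia (11, median 0.00, adjusted p = 0.698), endothelium (9, median 0.07, adjusted p = 0.295) and epithelium (8, median 0.03, adjusted p = 0.317) had no call with limma. Of 8 housekeeping genes 1 rose and 0 fell (1 and 1 over the list alone; median -0.07, adjusted p = 0.860), and that median turned positive with quantile normalization or cyclic loess (0.05 and 0.08), as did that of NF-kB factors (0.10 with each). With quantile normalization alone the medians of lipid storage (0.01) and neural stem genes (0.00) turned positive. Median, mean and test differed in sign for pH regulation, lipid storage, NF-kB factors, and markers of astrocytes and microglia.

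Across all genes, 480 rose and 1274 fell in hypoxia, of which 304 and 831 changed at least 1.5-fold. The 3 hypoxic values lay entirely above or below the 3 normoxic ones in 38.4% of genes, where chance gives 10%. Rises made up 27.4% of the calls on the deposited scale but 44.1% after quantile normalization (946 up, 1200 down), 45.1% after cyclic loess (1059 and 1289) and 34.8% with arrays centred on their medians (767 and 1438). Without normoxia replicate 1, 2 or 3 the rises numbered 289, 317 and 279 and the falls 517, 814 and 557. Falls numbered 503 and 771 without hypoxia control replicate 2 or 3.

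**Figure D3:**
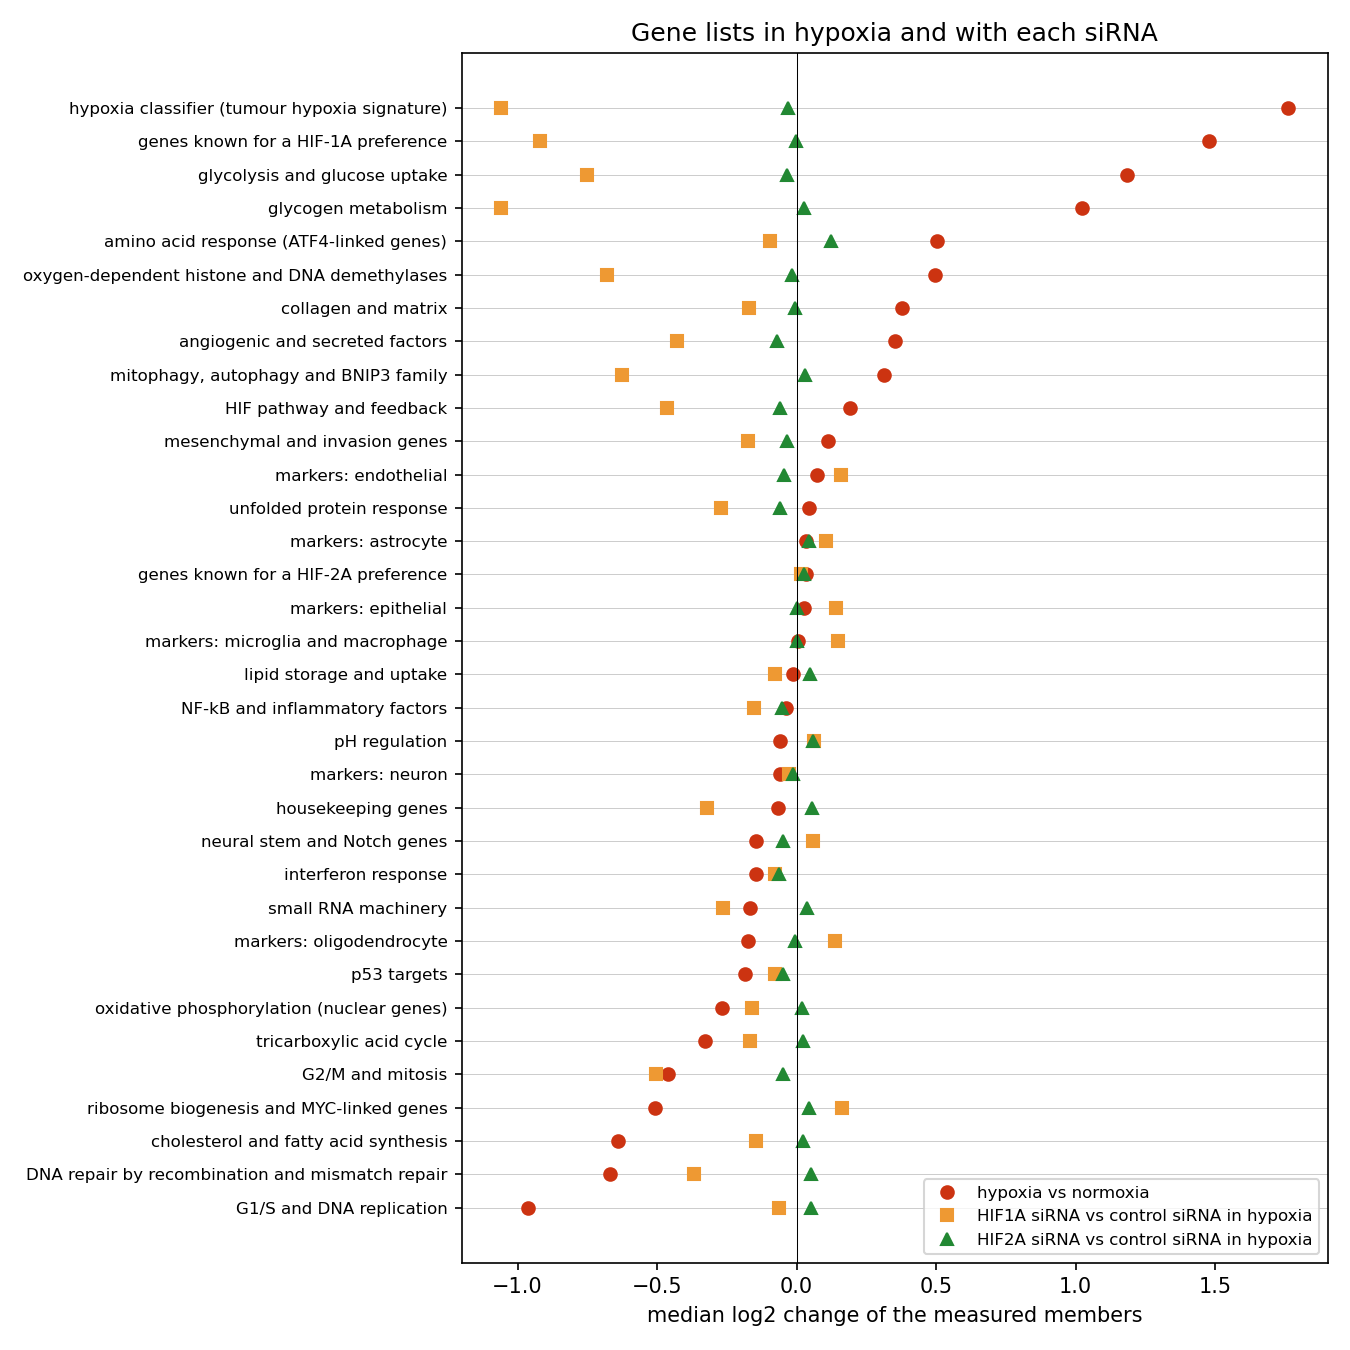
Median log2 change of the measured members of each of the 34 gene lists for hypoxia against normoxia (circles), HIF1A siRNA against control siRNA (squares) and HIF2A siRNA against control siRNA (triangles), sorted by the hypoxic change. Glycolysis lies at 1.18, -0.75 and -0.04, G1/S genes at -0.96, -0.06 and 0.05.

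HIF1A siRNA in hypoxia, set against control siRNA to ask what depends on HIF-1A, lowered the genes that hypoxia had raised most. BEND5 fell 10.2-fold (log2 change -3.36, SE 0.21, n = 3 per group, adjusted p = 5.7e-05), NRN1, a neuritin, 6.47-fold (-2.69, SE 0.21) and TMEM45A 6.24-fold (-2.64, SE 0.25). HILPDA (-2.17), STC1 (-2.15), FAM162A (-2.13), ANGPTL4 (-2.10) and PPP1R3C (-1.97) followed, each with all 3 arrays below the controls. ARLN also fell by this rule (-2.95), but without hypoxia control replicate 1 its adjusted p was 0.062. Among the largest rises were 4 genes that hypoxia had lowered: TAF9B (1.13, SE 0.14, adjusted p = 0.0011), CCL2 (1.13, SE 0.19, adjusted p = 0.0063), the antigen-loading gene HLA-DMB (1.08, SE 0.17, adjusted p = 0.0045) and S100B (0.85, SE 0.13, adjusted p = 0.0029). The other 6 of the 10 largest rises, KRTAP15-1, KRTAP10-7, MS4A1, NPBWR2, MYCN and BHLHA15, lay between 1.12 and 0.85, and each lost its call without HIF1A siRNA replicate 3 and without 1 or more hypoxia control replicates (highest adjusted p 0.117). KRTAP15-1 and NPBWR2 averaged 3.93 and 4.47 with control siRNA, below the lower quartile of every array.

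Several lists linked to HIF passed camera as falls. Of 19 glycolytic genes, 13 fell and 0 rose (16 and 0 over the list alone; median -0.75, adjusted p = 1.5e-10, adjusted p = 0.346 with an estimated correlation), among them ALDOC (-1.82), ENO2 (-1.78), PFKFB4 (-1.42) and HK1 (-1.22). In glycogen metabolism 6 of 8 fell and 0 rose by either adjustment (median -1.06, adjusted p = 2.6e-06, adjusted p = 0.352 with an estimated correlation), with GYS1 at -1.80 and the branching enzyme GBE1 at -1.23. The HIF pathway list had 5 falls among 12 (10 over the list alone; median -0.47, adjusted p = 2.3e-04, adjusted p = 0.399 with an estimated correlation), including BHLHE41 (-1.75) and MXI1 (-1.28). Of 13 demethylases, 8 fell (10 over the list alone; median -0.68, adjusted p = 2.6e-06, adjusted p = 0.399 with an estimated correlation), led by TET1 (-1.65), KDM4C (-1.34) and JMJD6 (-1.08). Angiogenic factors had 12 falls among 25 (16 over the list alone; median -0.43, adjusted p = 2.8e-07, adjusted p = 0.361 with an estimated correlation), including IGFBP5 (-1.28) and IGFBP3 (-1.19). The mitophagy list had 6 falls among 11 by either adjustment (median -0.63, adjusted p = 8.9e-04, adjusted p = 0.346 with an estimated correlation), with BNIP3L at -1.10 and the autophagy gene MAP1LC3B at -0.89. The classifier had 11 falls among 13 (12 over the list alone; median -1.06, adjusted p = 1.4e-08, adjusted p = 0.346 with an estimated correlation) and the HIF-1A preference list 14 among 18 (16 over the list alone; median -0.92, adjusted p = 2.1e-11, adjusted p = 0.346 with an estimated correlation). None of these 8 lists had a rise. With quantile normalization each still passed camera with a smaller fall, such as -0.35 for mitophagy, -0.26 for angiogenic factors and -0.30 for the HIF pathway. In the HIF-2A preference list LOXL2 (-0.53) and FLT1 (-0.78) fell and 0 rose (4 and 0 over the list alone; median 0.01, adjusted p = 0.819). Both calls were lost without hypoxia control replicate 1 (highest adjusted p 0.077 and 0.149).

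Other lists moved less or in part with the scaling. Collagen and matrix genes had 7 falls and 0 rises among 22 (8 and 0 over the list alone; median -0.17, adjusted p = 0.0389, adjusted p = 0.726 with an estimated correlation), PLOD2 (-1.08), P4HA1 (-1.06) and P4HA2 (-1.05) among them. That list call was lost with quantile normalization (adjusted p = 0.0870), with cyclic loess, where the median turned to 0.01 (adjusted p = 0.143), and without hypoxia control replicate 2 (adjusted p = 0.0924) or HIF1A siRNA replicate 2 (adjusted p = 0.10). The unfolded protein response had 6 falls and 0 rises among 19 by either adjustment (median -0.27, adjusted p = 0.0064, adjusted p = 0.682 with an estimated correlation). DNAJC3, HERPUD1, EDEM1 and SEL1L, its largest falls, each lost the call without hypoxia control replicate 1 or HIF1A siRNA replicate 3 (highest adjusted p 0.183). G2/M genes shifted down as a list (median -0.50, adjusted p = 0.00117, adjusted p = 0.735 with an estimated correlation) with 2 of 28 called, CCNB2 and DLGAP5, and 0 over the list alone. Those 2 calls were lost without HIF1A siRNA replicate 3, among other arrays (highest adjusted p 0.185), and the list did not pass fry (adjusted p = 0.125). Its median was -0.26 with quantile normalization and -0.28 with cyclic loess. Microglial markers, with 0 of 11 called by limma, passed as a rise (median 0.15, adjusted p = 0.0228, adjusted p = 0.599 with an estimated correlation). They did not pass with fry (adjusted p = 0.159), with quantile normalization (adjusted p = 0.160), with cyclic loess (adjusted p = 0.219), or without hypoxia control replicate 1 (adjusted p = 0.137) or HIF1A siRNA replicate 3 (adjusted p = 0.0524). Some of these markers were dim in hypoxia with control siRNA: AIF1 averaged 3.90, P2RY12 3.46 and PTPRC 2.36, below the lower quartile of every array. CD68, TYROBP and CSF1R did not lie below it. The 2859 dimmest genes with no response to hypoxia (unadjusted p over 0.2) had a median of 0.10 with HIF1A siRNA.

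G1/S genes, the largest group of falls in hypoxia, had 0 calls among 30 with limma (median -0.06, adjusted p = 0.505), and passed as a rise with quantile normalization (median 0.18, adjusted p = 0.0426), cyclic loess (0.16, adjusted p = 0.0092) and without HIF1A siRNA replicate 3 (0.11, adjusted p = 0.0188). Ribosome biogenesis genes had 2 rises and 2 falls among 14 by either adjustment (median 0.16, adjusted p = 0.198), and likewise passed as a rise with quantile normalization (0.43, adjusted p = 0.0278), cyclic loess (0.40, adjusted p = 0.0092) and without that array (0.32, adjusted p = 0.0497). RRS1 rose (0.58) and the methyltransferase FBL fell (-0.80). In the mesenchymal list 8 of 22 fell and 0 rose (10 and 2 over the list alone; median -0.17, adjusted p = 0.0727), among them SNAI2, a transcription factor of epithelial-mesenchymal transition (-0.85). The list passed with fry (adjusted p = 0.0227), with quantile normalization (median -0.14, adjusted p = 0.0448), without hypoxia control replicate 1 (adjusted p = 0.0493) and without HIF1A siRNA replicate 3 (adjusted p = 0.0497).

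The remaining lists did not pass camera with HIF1A siRNA, though lipid storage and NF-kB factors passed fry as falls (adjusted p = 0.0260 and 0.0466). ATF4-linked genes had 2 falls among 25 (1 over the list alone; median -0.10, adjusted p = 0.500), with VLDLR down (-1.62). Cholesterol and fatty acid synthesis had 1 rise, fatty acid synthase FASN (0.56), and 3 falls among 19 by either adjustment (median -0.15, adjusted p = 0.416). ACLY, which makes acetyl-CoA from citrate, fell (-0.69). Lipid storage had 2 falls among 12, HILPDA and VLDLR, by either adjustment (median -0.08, adjusted p = 0.383). NF-kB factors had 1 rise, CCL2, and 4 falls among 19 by either adjustment (median -0.15, adjusted p = 0.475), with PTGS2 at -1.63 and IL1A at -1.44. The interferon list had 4 falls among 24 by either adjustment (median -0.08, adjusted p = 0.374), p53 targets 2 among 17, led by TP53INP1 (-1.09) (median -0.08, adjusted p = 0.826), and neural stem genes 1 among 16, L1CAM (-0.77) (median 0.06, adjusted p = 0.374), each the same over the list alone. CA12, at -0.38, was the call among 4 genes of pH regulation (median 0.06, adjusted p = 0.826) and was lost without 10 of the 12 arrays taken singly, including HIF1A siRNA replicates 1 and 3 (highest adjusted p 0.192).

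Oxidative phosphorylation had 1 rise among 27 and 0 over the list alone (median -0.16, adjusted p = 0.826), the tricarboxylic acid cycle 1 fall among 12 by either adjustment (median -0.17, adjusted p = 0.350), and neuronal markers 1 fall among 8 by either adjustment (median -0.03, adjusted p = 0.696). These 3 calls, of CYC1 (0.49), DLST (-0.88) and MAP2 (-0.66), were lost without hypoxia control replicate 1, among other arrays (highest adjusted p 0.188, 0.127 and 0.190). Astrocyte markers had 1 rise among 8, S100B, by either adjustment (median 0.11, adjusted p = 0.162). DNA repair (median -0.37, adjusted p = 0.383), small RNA machinery (-0.26, adjusted p = 0.299), and markers of oligodendrocytes (0.14, adjusted p = 0.116), endothelium (0.16, adjusted p = 0.101) and epithelium (0.14, adjusted p = 0.139) had no call with limma. Endothelial markers passed camera as higher with the filter on dim genes (0.17, adjusted p = 0.0315), and epithelial markers without HIF1A siRNA replicate 1 (0.22, adjusted p = 0.0485). Housekeeping genes had 0 of 8 called, and 2 falls over the list alone (median -0.32, adjusted p = 0.350). Median, mean and test differed in sign for pH regulation, the HIF-2A preference list, G1/S, ribosome biogenesis, neural stem genes and neuronal markers. With quantile normalization or cyclic loess the medians of oxidative phosphorylation (0.08 and 0.06), the tricarboxylic acid cycle (0.09 and 0.07), p53 targets (0.14 and 0.12), cholesterol synthesis (0.03 and 0.02), lipid storage (0.05 and 0.02) and neuronal markers (0.04 and 0.00) turned positive, and with quantile normalization alone that of NF-kB factors (0.02).

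In all, 122 genes rose and 1451 fell with HIF1A siRNA, and the groups lay apart in 30.8% of genes (chance 10%). Rises made up 7.76% of calls as deposited, 39.2% after quantile normalization (726 up, 1124 down), 31.5% after cyclic loess (545 and 1183) and 28.6% with centred arrays (509 and 1272). Quantile normalization moved the median of all genes from -0.05 to 0.07. Without hypoxia control replicate 1 or 3 the falls numbered 366 and 741, without HIF1A siRNA replicate 2 or 3 they numbered 2450 and 539, and without normoxia replicate 2 or 3 they numbered 967 and 952. The rises numbered 24 and 54 without hypoxia control replicate 1 or 3, 71, 198 and 68 without HIF1A siRNA replicate 1, 2 or 3, 70 without HIF2A siRNA replicate 1, and 74, 70 and 65 without normoxia replicate 1, 2 or 3.

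HIF2A siRNA in hypoxia, the same question for HIF-2A, changed 1 gene by limma, its target EPAS1, and 502 genes (3.53%) had an unadjusted p under 0.05. Quantile normalization and cyclic loess each gave 1 rise and 3 falls, and centred arrays 0 and 3. The 10 genes with the largest rises in hypoxia lay between -0.53 for CP (SE 0.19, n = 3 per group) and 0.31 for TMEM45A (SE 0.25), with BEND5 at 0.09 (SE 0.21) and ALDOC at 0.02 (SE 0.15). The list members with the smallest adjusted p were IGFBP3 (-0.56, adjusted p = 0.81), SNAI2 (-0.51, adjusted p = 0.818), the glycolytic regulator PFKFB3 (-0.51, adjusted p = 0.858) and the cytokine IL1B (0.41, adjusted p = 0.919), none of them called. The groups lay apart in 9.36% of genes, close to the 10% that chance gives. For 300 of the 304 hypoxia-induced genes the 95% interval of the change excluded a 2-fold fall. No member of the 34 lists was called over all genes. Adjusted over the list alone, 1 member fell in each of glycolysis, the classifier, the HIF-1A preference, the HIF-2A preference and the mesenchymal list, 2 fell among angiogenic factors, and 1 rose among NF-kB factors.

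The ATF4-linked genes passed camera as a slight rise with HIF2A siRNA (median 0.12, adjusted p = 0.0015, adjusted p = 0.951 with an estimated correlation). They did not pass fry (adjusted p = 0.969), nor camera without hypoxia control replicate 3 (median 0.09, adjusted p = 0.20). The other list medians lay between -0.07 for angiogenic factors and 0.06 for pH regulation and passed no test. Quantile normalization and cyclic loess turned the median of epithelial markers from 0.00 to -0.02. Without hypoxia control replicate 1, G1/S genes (median 0.12), DNA repair (0.19) and small RNA machinery (0.19) passed as rises, each with adjusted p = 0.0329. Median, mean and test differed in sign for glycogen metabolism, demethylases, collagen, the HIF-2A preference list, the tricarboxylic acid cycle, NF-kB factors, and markers of neurons, oligodendrocytes and microglia.

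The siRNAs were also compared directly. The induced genes most lowered by HIF1A siRNA relative to HIF2A siRNA were BEND5 (log2 difference -3.45, SE 0.21, n = 3 per group, adjusted p = 6.6e-05), TMEM45A (-2.96, SE 0.25), NRN1 (-2.94, SE 0.21), HILPDA (-2.33), FAM162A (-2.32), the receptor gene GPR160 (-2.17), PPP1R3C (-2.06), NEBL (-2.01), LINC01587 (-1.96) and GPR146 (-1.94). GPR160 and NEBL averaged 3.32 and 3.40 with HIF1A siRNA, below the lower quartile of every array (4.73 to 4.79), so the size of their differences is uncertain. NEBL lost its call without HIF2A siRNA replicate 3 (adjusted p = 0.055), as did ARLN (-3.07, adjusted p = 0.060). In the other direction the 5 largest were TMEM242 (1.30), TAF9B (1.18, SE 0.14, adjusted p = 0.0011), SSTR5 (1.15), EPAS1 (1.11) and OR1A1 (1.09). TMEM242 lost its call without HIF2A siRNA replicate 1 (adjusted p = 0.052). SSTR5 and OR1A1 lost theirs without HIF2A siRNA replicate 1 or 3, and OR1A1 without 6 further arrays (highest adjusted p 0.085 and 0.159). With HIF2A siRNA TMEM242, SSTR5 and OR1A1 averaged 4.08, 4.41 and 3.18, below those quartiles too, and OR1A1 also did with HIF1A siRNA (4.28). EPAS1 was the only induced gene called lower with HIF2A siRNA than with HIF1A siRNA.

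The lists that fell with HIF1A siRNA were lower than with HIF2A siRNA as well. Glycolysis had 11 lower members of 19 (15 over the list alone; median -0.60, adjusted p = 5.4e-09), glycogen metabolism 6 of 8 (median -0.89, adjusted p = 2.1e-06), demethylases 8 of 13 (11 over the list alone; median -0.72, adjusted p = 1.6e-06), angiogenic factors 11 of 25 (14 over the list alone; median -0.36, adjusted p = 4.8e-06), the HIF-1A preference list 13 of 18 (15 over the list alone; median -0.85, adjusted p = 2.3e-10) and the classifier 8 of 13 (10 over the list alone; median -0.97, adjusted p = 3.9e-07). The mitophagy list (median -0.67, adjusted p = 8.3e-04) and the HIF pathway list (median -0.53, adjusted p = 0.0015), with 6 lower members each, passed too (over the list alone 6, and 8 with 1 higher). With an estimated correlation the adjusted p of these 8 lists lay between 0.373 and 0.528. With quantile normalization the medians of the mitophagy and HIF pathway lists were -0.40 and -0.27, and both still passed camera. Genes known for a HIF-2A preference had 3 lower members and 0 higher (4 over the list alone; median -0.01, adjusted p = 0.872). Collagen, G2/M, unfolded protein response and ATF4-linked genes passed as lower (medians -0.18, -0.51, -0.27 and -0.21) and microglial markers as higher (0.14). With an estimated correlation the adjusted p was 0.727 for the first 4 and 0.549 for the last. The G2/M median was -0.25 with quantile normalization. With quantile normalization the adjusted p was 0.0943 for collagen, whose median turned to 0.01, 0.0943 for ATF4-linked genes and 0.132 for microglial markers, and cyclic loess also ended these 3 calls and that of the unfolded protein response (adjusted p = 0.0632). Without HIF1A siRNA replicate 3 the adjusted p of G2/M, ATF4-linked genes and microglial markers was 0.056, 0.066 and 0.062, and without HIF1A siRNA replicate 2 that of collagen was 0.065. G2/M, ATF4-linked genes and microglial markers did not pass fry (adjusted p = 0.130, 0.0505 and 0.134), while lipid storage, NF-kB factors and mesenchymal genes passed fry as lower (adjusted p = 0.0146, 0.0395 and 0.0409). The other lists did not pass camera, with medians between -0.39 for small RNA machinery and 0.16 for endothelial markers. Of these, G1/S genes passed as higher with cyclic loess (median 0.11, adjusted p = 0.0459) and with quantile normalization without HIF1A siRNA replicate 3 (0.21, adjusted p = 0.0031). DNA repair passed as lower without HIF1A siRNA replicate 2 (-0.57, adjusted p = 0.0326), and endothelial markers as higher without HIF2A siRNA replicate 2 (0.19, adjusted p = 0.0406) or with the filter on dim genes (0.17, adjusted p = 0.010). With quantile normalization and cyclic loess the medians of the HIF-2A preference list (0.12 and 0.06), oxidative phosphorylation (0.10 with each), G1/S (0.11 with each), ribosome biogenesis (0.22 and 0.20), p53 targets (0.16 and 0.10) and neuronal markers (0.09 and 0.04) turned positive. With quantile normalization alone those of pH regulation (0.05), the tricarboxylic acid cycle (0.01), cholesterol synthesis (0.00) and NF-kB factors (0.03) did. G1/S, ribosome biogenesis, p53 targets and neuronal markers had a negative median and a positive direction in the test.

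Genes higher with HIF1A than with HIF2A siRNA numbered 128 and lower ones 1214, with groups apart in 30.5% of genes (chance 10%). The higher ones were 9.54% of calls as deposited, 44.9% after quantile normalization (799 and 981), 34.2% after cyclic loess (530 and 1019) and 37.6% with centred arrays (654 and 1086). Quantile normalization moved the median of all genes from -0.06 to 0.08. Lower genes numbered 254 and 295 without HIF2A siRNA replicate 1 or 3, 2338 and 383 without HIF1A siRNA replicate 2 or 3, and 776 and 720 without normoxia replicate 2 or 3. Higher genes numbered 14, 243 and 11 without HIF2A siRNA replicate 1, 2 or 3, 219 and 61 without HIF1A siRNA replicate 2 or 3, 77 without hypoxia control replicate 3, and 69, 64 and 64 without normoxia replicate 1, 2 or 3.

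**Figure D4:**
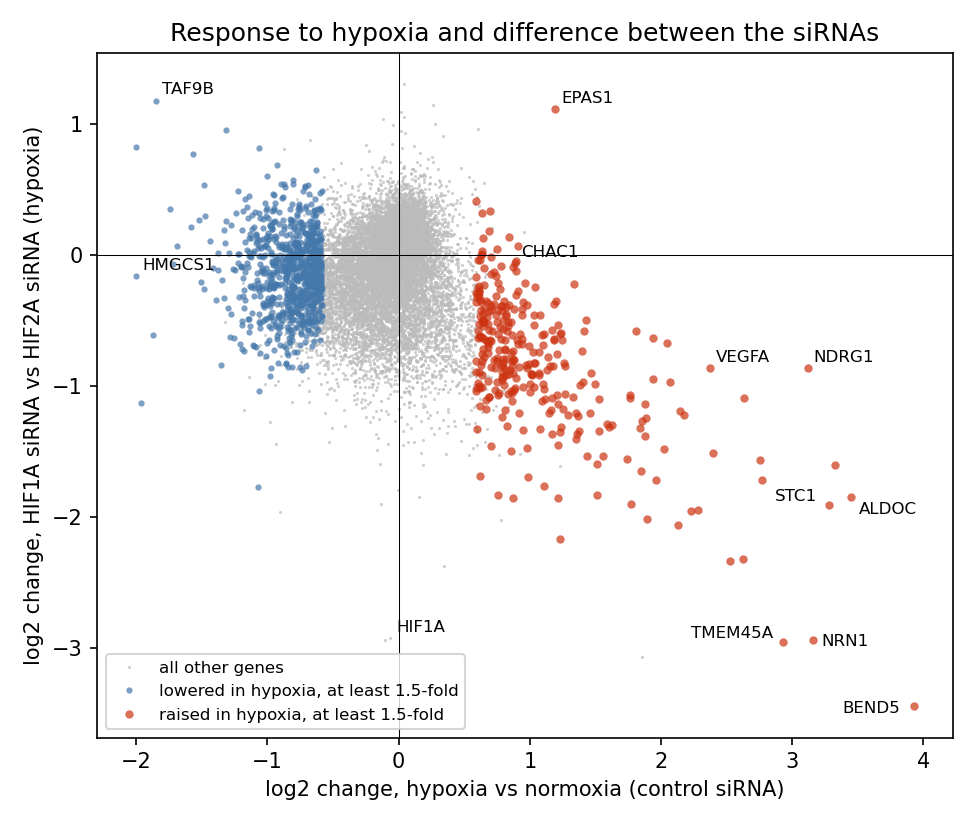
Log2 change in hypoxia with control siRNA (x axis) against the log2 difference between HIF1A siRNA and HIF2A siRNA in hypoxia (y axis), with a point for each of 14232 genes; red, raised at least 1.5-fold in hypoxia (304), blue, lowered at least 1.5-fold (831), grey, all others. BEND5 lies at 3.93 and -3.45, and EPAS1 lies above 0 on the y axis, at 1.11.

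Hypoxia-induced genes were then sorted by siRNA, which is not a sorting by subunit, since EPAS1 was also lower with HIF1A siRNA. Of the 304, 262 (86.2%) were lower with HIF1A siRNA than with control siRNA, and 1 of these, EPAS1, was lower with HIF2A siRNA as well. The other 42 were called lower with neither. Tested directly, 229 (75.3%) were lower with HIF1A than with HIF2A siRNA. With HIF1A siRNA 72 remained higher than in normoxia, and with HIF2A siRNA 251. Of the 831 lowered genes, 28 were higher with HIF1A siRNA than with control siRNA, TAF9B, CCL2, HLA-DMB and S100B among them, and 5 were lower still. With HIF2A siRNA 0 were higher by limma. Most of the 831 remained lower than in normoxia, 776 with HIF1A siRNA and 563 with HIF2A siRNA. Lower genes prevailed generally with HIF1A siRNA against normoxia (664 higher and 4322 lower over all genes). In the direct comparison 17 of the 831 (2.05%) were higher with HIF1A than with HIF2A siRNA and 31 (3.73%) lower. HLA-DMB was not called there (0.52, adjusted p = 0.0797). Over all genes that comparison gave 128 higher and 1214 lower, so lower genes prevailed in it generally. In 100 simulated draws with unchanged siRNA groups, induced genes were chosen anew each time, so their number was not fixed at 304. A median of 0 of them were lower, with 308 in the highest draw and at least 262 in 1 draw. Independent lists would share 31.0 induced and lower genes and 7.12 lowered and higher ones. Changes in hypoxia and with HIF1A siRNA correlated at r = -0.257 across genes, which are not independent replicates, against a median of -0.102 in the simulation (covariance -0.0337 against a median of -0.0060). The lowest simulated correlation was -0.578, so draws of this kind with unchanged groups can pass the observed value. Each draw took the departures of whole arrays from their group means, with replacement, so an array could occur more than once in a group. How much the extreme draws owe to this was not tested. The 3 control arrays cannot be parted into groups of at least 2, so the exact part of the excess that comes from the shared controls is not known. HIF2A siRNA was set against the same control arrays, and 1 of the 304, its target EPAS1, was lower there. This argues against the shared controls as the source of most of the 262. The direct comparison of the siRNAs does not use the control arrays as its reference, and a separate run of 100 draws of the same kind gave at most 98 lower genes there.

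Over 303 induced genes, EPAS1 left out, a median of 13.2% of the hypoxic rise was left with HIF1A siRNA (quartiles -12.3% and 34.4%) and 92.4% with HIF2A siRNA (78.0% and 104.6%). Array by array the median share was 22.7%, 22.3% and -8.01% with HIF1A siRNA (SD 17.6, n = 3) and 100.3%, 78.0% and 97.9% with HIF2A siRNA (SD 12.2). Quantile normalization put the first at 39.0% and cyclic loess at 38.1%, each over induced genes chosen anew after that normalization. Without HIF1A siRNA replicate 2 it was 7.44%, and without hypoxia control replicate 1 19.8%, where 159 induced genes were lower with HIF1A siRNA. Without HIF2A siRNA replicate 1, 136 were lower than with HIF2A siRNA.

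Each siRNA group was also set against normoxia with control siRNA. These comparisons differ in both oxygen and siRNA, so effects of the siRNA stand in them beside what remained of the hypoxic response. With HIF1A siRNA, NDRG1 was still 2.00 higher on the log2 scale (SE 0.11, n = 3 per group, adjusted p = 1.5e-05), ALDOC 1.62, VEGFA 1.44, HK2, a hexokinase, 1.41, and CHAC1, which degrades glutathione, 1.25 (SE 0.22, adjusted p = 0.0043). HIF1A itself was lowest (-3.19), followed by TUBA1B (-3.08), H2BC3 (-2.96), RAP1B (-2.36) and CHORDC1 (-2.23). TUBA1B, RAP1B and CHORDC1 lost their calls without HIF1A siRNA replicate 1 or 3 or normoxia replicate 1 or 3 (highest adjusted p 0.137, 0.094 and 0.122), and with HIF1A siRNA they averaged 4.20, 4.66 and 2.82, below the lower quartile of every array, as MRGPRX4 did with HIF2A siRNA (4.40). With HIF2A siRNA the largest rises over normoxia were BEND5 (4.01, SE 0.21), ALDOC (3.47), NRN1 (3.41), TMEM45A (3.24) and STC1 (3.05), and the largest falls MRGPRX4 (-2.20), TAF9B (-1.90), H2BC3 (-1.84), LONRF2 (-1.60) and THEM4 (-1.58). H2BC3 lost this call without HIF2A siRNA replicate 1 or 2 or any normoxia replicate (highest adjusted p 0.118).

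With HIF1A siRNA 664 genes were higher and 4322 lower than in normoxia (13.3% higher), with groups apart in 54.5% of genes (chance 10%), and with HIF2A siRNA 405 and 967 (29.5% higher), with groups apart in 36.7%. Quantile normalization gave 2241 and 2082 (51.8%) for HIF1A siRNA, moving the median of all genes from -0.12 to 0.08, and 768 and 903 (46.0%) for HIF2A siRNA. Cyclic loess gave 1795 and 2216 (44.8%) and 855 and 985 (46.5%), and centring 2882 and 3306 (46.6%) for HIF1A siRNA. With HIF1A siRNA, lower genes numbered 2429 without its replicate 3 and 2212 without normoxia replicate 1, and higher ones 395 and 294 without its replicate 1 or 3 and 149, 346 and 255 without normoxia replicate 1, 2 or 3. With HIF2A siRNA, higher genes numbered 241 without its replicate 1 and 241, 253 and 242 without normoxia replicate 1, 2 or 3. Lower ones numbered 551 and 364 without its replicate 1 or 2, 347, 522 and 368 without normoxia replicate 1, 2 or 3, and 1509 without HIF1A siRNA replicate 3.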

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

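Of the tests in this part, the correlation with the range of the arrays and the regroupings of the arrays were chosen before their results were seen. The test without the third HIF1A siRNA array, the brightness test, the matched lists, the simulation of the direct comparison and the EPAS1 tests were chosen only after the result was seen, and the pair of control arrays for the correlation was picked from ranges already seen.

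Probe sets that the named genes leave out also changed. In hypoxia, 235 of the 5171 probe sets with no gene symbol here passed the test (49 up, 186 down, largest rise 3.27), and 223 of the 2408 with several symbols did (67 up, 156 down, largest rise 2.38). With HIF1A siRNA, 205 with no symbol passed (56 up, 149 down) and 205 with several symbols (16 up, 189 down). With HIF2A siRNA limma called 0 in each class. The transcripts behind these probe sets were not analysed here.

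HIF1A siRNA gave 122 rises and 1451 falls. Against a single odd array stands the share of rises without the third HIF1A siRNA array, 11.2% against 7.76% with it (68 rises and 539 falls). A narrower signal range stays open for part of the pattern: over 8213 genes with no response to hypoxia (unadjusted p over 0.2), the difference between HIF1A and HIF2A siRNA, which leaves the control arrays out, correlated at r = 0.707 (Spearman 0.710) with the difference between control array 2, which has a narrow range, and control array 1. Genes are not independent replicates, and other pairs within groups gave r between 0.082 and 0.588; quantile normalization, which removes differences in range, gave 39.2% rises. A broad loss of transcripts from abundant genes without HIF-1A cannot be told apart from this, because the 1417 brightest of those genes had a median shift of -0.34 with HIF1A siRNA against control siRNA, -0.04 with HIF2A siRNA and -0.16 between the same control arrays.

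Hypoxia-induced genes fell with HIF1A siRNA. The range of the arrays as the whole cause is argued against by lists matched on brightness: with quantile normalization the induced genes had a median of -0.61 between HIF1A and HIF2A siRNA and matched lists 0.03, a difference of -0.64 that none of 10000 random lists reached. The shared hypoxic control is argued against by the direct comparison, in which 229 induced genes were lower with HIF1A siRNA and simulated draws gave at most 98. An effect of the HIF1A siRNA other than through HIF-1A stays open, since the labels give a single siRNA group for each target. EPAS1 was lower in the HIF1A siRNA group as well (log2 change -1.48 against control siRNA). No group had HIF1A lowered alone, so a fall of HIF1A cannot be told apart here from a fall of both. A fall of EPAS1 alone as the cause is argued against by the HIF2A siRNA group. There EPAS1 averaged 7.12, against 8.23 with HIF1A siRNA, and HIF1A was not called changed. A median of 92.4% of the hypoxic rise was left in that group, against 13.2% with HIF1A siRNA. A need for HIF-1A in the hypoxic rise of these genes may explain the pattern and remains a hypothesis.

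EPAS1 fell with HIF1A siRNA. Against the range as the whole cause, the fall was -1.22 with quantile normalization (adjusted p = 2.6e-04), and 0.2% of the 500 genes nearest in brightness fell further. Against normoxia EPAS1 stood at -0.29 with HIF1A siRNA (adjusted p = 0.148), so an action of that siRNA on the EPAS1 transcript itself can be neither shown nor excluded from these arrays. A need for HIF-1A in the hypoxic rise of EPAS1 also stays open: the share of the rise left, -24.1%, restates the fall, and an action of the siRNA on EPAS1 would give the same value.

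The 6 arrays of each comparison can be parted in 10 ways, too few for a share under 0.05. The number of genes called in the real grouping was the highest in each case, 1 of 10. The real count and the highest of the other groupings were 1754 and 0 for hypoxia, 1573 and 0 for HIF1A siRNA against control siRNA, 1 and 0 for HIF2A siRNA against control siRNA, 4986 and 0 for HIF1A siRNA against normoxia, 1372 and 0 for HIF2A siRNA against normoxia, and 1342 and 2 between the siRNAs.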

How the results depend on the processing

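Cyclic loess, and quantile normalization without the third HIF1A siRNA array, were chosen only after the result was seen. No called value of a named gene or list passed in the opposite direction in the settings where it was followed. Named genes were not followed with all probe sets or other thresholds. Lists were not followed in those settings, with centred arrays, without moderation or in fits of the compared groups. Called genes outside the named ones were not checked for direction. Medians of lists did change sign, and those that did so with quantile normalization or cyclic loess are given with the lists. The cause was not tested for the changes below, except that stricter thresholds call fewer genes by construction.

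Counts beyond 1.5 times their value were as follows, with rises before falls. Induced genes were chosen anew in each setting, also for the share of the rise left. Quantile normalization gave 946 rises in hypoxia, 726 with HIF1A siRNA against control siRNA, 1 and 3 with HIF2A siRNA against control siRNA, 2241 and 2082 with HIF1A siRNA against normoxia, 768 rises with HIF2A siRNA against normoxia and 799 between the siRNAs, and 39.0% of the hypoxic rise left with HIF1A siRNA instead of 13.2%. Arrays centred on medians gave 767, 509, 3 falls with HIF2A siRNA, 2882 with HIF1A siRNA against normoxia and 654 between the siRNAs. Cyclic loess gave 1059, 545, 1 and 3, 1795 and 2216, 855 and 530 in the order of the quantile values, 465 induced genes and 38.1% left. Quantile normalization without the third HIF1A siRNA array gave 1014 rises, 222 and 497, 1 and 3, 809 falls with HIF1A siRNA against normoxia, 819 rises with HIF2A siRNA against normoxia, 369 falls between the siRNAs and 39.2% left.

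Without variance moderation falls numbered 871 for HIF1A siRNA against control siRNA and 604 between the siRNAs. Fits of the compared groups alone gave 1947 falls in hypoxia, 3 and 134 for HIF1A siRNA against control siRNA, 316 rises for HIF1A siRNA and 1607 falls for HIF2A siRNA against normoxia, and 4 and 123 between the siRNAs. Induced genes lower with HIF1A siRNA then numbered 105, and 88 against HIF2A siRNA. Array weights gave 945 and 2794 in hypoxia, 56 and 735 for HIF1A siRNA, and 998 and 2216 for HIF2A siRNA against normoxia. With the replicate number as a block, 85 genes were higher with HIF1A than HIF2A siRNA. After group means were removed, 6 of 18 pairs of the same number correlated above 0.1 (-0.488 to 0.597), and 5 of 12 arrays correlated best with their own number. The labels do not say whether arrays of the same number were processed together, and these correlations cannot decide it.

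A 1.5-fold minimum gave 304 and 831 in hypoxia, 39 rises with HIF1A siRNA, 81 and 2880 for HIF1A siRNA against normoxia, 593 falls for HIF2A siRNA against normoxia and 35 rises between the siRNAs. A 2-fold minimum gave 117 and 154, 5 and 291, 12 and 678, 110 and 78, and 5 and 237, in the order hypoxia, HIF1A siRNA, HIF1A siRNA against normoxia, HIF2A siRNA against normoxia, and between the siRNAs. An adjusted p under 0.01 gave 245 and 460, 15 and 356, 67 and 1844, 214 and 303, and 7 and 265 in the same order, with 154 induced genes lower with HIF1A siRNA and 121 lower than with HIF2A siRNA. Of 117 genes induced at least 2-fold, 112 were lower with HIF1A siRNA and 108 lower than with HIF2A siRNA; with no fold limit 480 were induced.

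Leaving out each array in turn gave 279 to 587 rises and 503 to 1878 falls in hypoxia, 24 to 198 and 366 to 2450 for HIF1A siRNA, 0 to 0 and 1 to 1 for HIF2A siRNA, 149 to 703 and 2212 to 4580 for HIF1A siRNA against normoxia, 241 to 512 and 347 to 1509 for HIF2A siRNA against normoxia, and 11 to 243 and 254 to 2338 between the siRNAs. Induced genes numbered 243 to 323, of which 159 to 273 were lower with HIF1A siRNA, 1 to 1 with HIF2A siRNA, and 136 to 248 lower with HIF1A than HIF2A siRNA. The share of the rise left was 7.44% to 19.8% with HIF1A siRNA and 87.9% to 99.8% with HIF2A siRNA.

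Of 575 values of named genes, 528 kept their side of the threshold with quantile normalization (22 lost a call, 25 gained one), 532 with cyclic loess (22 and 21), 546 with centred arrays (8 and 21), 572 with an intensity trend (0 and 3), 525 without moderation (47 and 3), 479 in fits of the compared groups (90 and 6), 556 with the block (16 and 3) and 536 with weights (23 and 16). Of 278 calls, 99 ended without at least 1 array. Of 136 results of lists, 44 were called with the preset correlation and lost the call with an estimated one; 119 kept their side with fry (10 lost, 7 gained), 125 with quantile normalization (7 and 4) and 124 with cyclic loess (8 and 4).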

Other observations

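The test of ATF4-linked genes in this part, the shares by list, and the genes named in it outside the lists' rule, were chosen only after the result was seen.

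Among the 28 genes that hypoxia lowered at least 1.5-fold and that were higher with HIF1A than with control siRNA, several are given here, of which CTPS1 is also among the largest falls in hypoxia. Both comparisons use the hypoxic control arrays, so the direct difference between HIF1A and HIF2A siRNA is given as well. The vitamin transporter SLC5A6 changed by -1.49 in hypoxia and 0.74 with HIF1A siRNA, and the direct difference was 0.54 (adjusted p = 0.0362). The homeobox genes DLX1 (-1.01, 0.56 and 0.34, adjusted p = 0.0386) and DLX2 (-1.0, 0.65 and 0.60, adjusted p = 0.0179) were also called in the direct comparison. LRP8, an apolipoprotein E receptor (-1.52, 0.80 and 0.27, adjusted p = 0.225), CTPS1 (-1.74, 0.62 and 0.35, adjusted p = 0.175) and GLDC, of glycine breakdown (-1.10, 0.57 and 0.21, adjusted p = 0.380), were not.

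Among the 42 induced genes called lower with neither siRNA, CBS, of cysteine synthesis, changed by 1.34 in hypoxia and -0.18 with HIF1A siRNA. The serine enzyme PSAT1 changed by 1.23 and -0.32, asparagine synthetase ASNS by 0.89 and -0.02, CHAC1 by 0.88 and 0.36, the collagen gene COL1A1 by 0.77 and -0.14, and the alanyl-tRNA synthetase AARS1 by 0.63 and -0.01. Others of the 42 narrowly missed a call as lower with HIF1A siRNA by limma, such as CHD2 (-0.78, adjusted p = 0.0603), TF (-0.66, adjusted p = 0.0618) and DYNC1H1 (-0.60, adjusted p = 0.0696). A hypothesis is that the hypoxic rise of genes linked to ATF4, a factor of the amino acid response, may not need HIF-1A. The 9 induced members of that list were ASNS, CHAC1, TRIB3, PSAT1, VLDLR, STC2, PCK2, WARS1 and AARS1. A median of 69.4% of their rise was left with HIF1A siRNA, against 11.3% in the 294 other induced genes, and with quantile normalization 94.3% and 36.0%. The list was fixed before the values were seen, but it was picked from 34 lists because members stood among the 42 genes, so these shares restate that observation and leave the hypothesis untested. VLDLR (-1.62) and STC2 (-0.60) were called lower with HIF1A siRNA. The call of STC2 ended without hypoxia control replicate 1 or 3, HIF1A siRNA replicate 2 or 3, any HIF2A siRNA replicate, or normoxia replicate 1 or 3, taken singly (highest adjusted p 0.172).

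By list, the share of the rise left with HIF1A siRNA was 37.4% for 12 induced genes of glycolysis, 36.0% for 9 angiogenic factors, 42.4% for 8 collagen and matrix genes, 38.2% for 4 mitophagy genes, 41.2% for 9 classifier genes, 41.2% for 13 genes known for a HIF-1A preference, 7.53% for 5 genes of glycogen metabolism and 1.48% for 6 demethylases. Over all induced genes it was 13.2%. With quantile normalization and the same genes the shares were 47.3%, 48.1%, 57.1%, 51.1%, 56.6%, 47.0%, 23.8% and 25.6% in the same order. The 39.0% given above for quantile normalization was over induced genes chosen anew, a different set. With HIF2A siRNA the same lists kept 97.7%, 97.1%, 104.8%, 104.3%, 101.7%, 101.7%, 95.9% and 96.3%.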
